A study of Oryza sativa with 18 samples.

How the data were processed

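RNA was measured by sequencing in rice pistils from field grown plants of 3 genotypes: Balilla, BalillaORF5+ and BalillaORF3+ORF5+. Each genotype was sampled at the stages S1, S2 and S3 with 2 libraries per group, which made 9 groups and 18 libraries. Nothing in the labels says whether the 2 libraries of a group came from separate plants, and each was counted as 1 sample. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a TruSeq v2 kit. The labels do not state that strands were kept, so antisense transcripts could not be told apart from sense ones.

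Per the submitters' processing notes, reads were handled with TopHat, Cufflinks and Cuffdiff, without versions, on the IRGSP 1.0 genome build. The authors deposited 1 file per library with FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each gene, the bounds of their intervals and a status, per the file headers. The authors also deposited 6 comparison tables, 1 for each transgenic genotype against Balilla at each stage, with log2 fold change, p-value and q-value per gene. These tables list genes with a p-value under 0.05, and mark as significant those with a q-value under 0.05. The log2 fold change column of the authors' tables holds a placeholder where a group was at 0, so it was used for its sign and not as a measured size. The FPKM values were used as deposited, and every fold change, error and p below was computed from them unless the authors' deposited table is named.

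Each file held 55991 entries. The 9 entries of 4 repeated gene IDs were left out, and so were 64 entries with a status other than OK in some library, which left 55918 genes. A gene was tested when its FPKM was at least 1 in at least 2 of the 18 libraries, and 23503 genes passed this filter. Values were log2 transformed after adding 1. Depth could only be gauged: the deposited intervals imply 18060000 to 27960000 fragments per library (median 20070000), but the implied fragment number of a gene was whole within 0.05 for only 66.8% to 69.4% of values. No counting interval was therefore given for single genes.

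The tests used limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted over the 18 libraries, with 9 residual degrees of freedom, and the variances were moderated with a trend on expression (3.15 prior degrees of freedom). The 14 comparisons were each transgenic genotype against Balilla at each stage, the transgenic genotypes against each other at each stage, the mean of each of these differences over the stages, and S2 against S1 and S3 against S2 in Balilla. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided. A limma F test asked whether a genotype difference was the same at the 3 stages. Errors on log2 fold changes are standard errors from this model, and errors on FPKM are standard deviations with n = 2. The spread behind each p is that between these libraries, which may be only technical.

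Gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and most alternative settings. Of 7 lists with gene IDs, 1 held the S5 locus genes, and 6 were tested with limma's camera in the 9 genotype comparisons per stage, which made 54 list tests. They covered endoplasmic reticulum (ER) folding and the unfolded protein response (15 genes tested), programmed cell death (7), meiosis (15), carpel and ovule identity (8), stamen and lodicule identity (3), and tapetum and pollen (10). The stamen and tapetum lists stood for other organs or cells that a pistil sample could hold. Camera compares a list with all other genes, here with a preset correlation of 0.01 and again with the correlation estimated, and p was adjusted over the lists of a comparison.

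The files pair gene IDs with no symbols or descriptions, and 0 of the IDs in the files were found in the RefSeq table. The symbol of each list gene was paired with its ID from general knowledge. Of the 63 list genes, 62 were in the files and 46 had their symbol in the RefSeq table, 45 of these on the chromosome of the ID. All 85 pairs of list genes that could be compared for order along a chromosome had the same order. The exception on chromosome was DMC1B, whose identity is therefore less certain. A further 18 lists defined by words in gene descriptions were not applied, because no descriptions were at hand, among them a list for photosynthesis.

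The rule for named genes took ORF3, ORF4 and ORF5 of the S5 locus, up to 3 members of each list with the smallest adjusted p over the 6 comparisons with Balilla, and genes with the largest changes that have a symbol or description. ORF4 was not analysed here. The last part named no gene for want of symbols, so 4 IDs without a name were printed instead. Other list members are named where a small count asked for it, after their values were seen.

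The test was checked on simulated data, in which 200 genes were changed by a known amount. Each gene had the same spread in all groups, taken from the model, and genes varied independently. The real pairs differ in spread, with a median absolute log2 difference from 0.068 (BalillaORF3+ORF5+ S3) to 0.443 (BalillaORF3+ORF5+ S2). The rates that follow therefore hold for the simulated setting and may not hold for the real comparisons. At a log2 change of 1, limma recovered 59% to 67% of them, and at a log2 change of 2 it recovered 87% to 97%. Between 3.3% and 5.3% of calls were false and 0 had the wrong sign.

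The alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, rescaling of each library to equal sums, the replicate number as a block, the libraries of a comparison alone, and leaving out each library in turn. Chosen after seeing the data were a fit without both BalillaORF3+ORF5+ S2 libraries, a fit with each library's position on the Balilla stage course as a covariate, the repetition of some fits for further genes, and leaving out libraries for the list tests that passed. The position of a library was computed over all tested genes by projecting it on the line from the Balilla S1 mean (0) to the Balilla S3 mean (1). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.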

Results

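RNA levels were measured in rice pistils of the parent Balilla and of 2 transgenic genotypes, BalillaORF5+ and BalillaORF3+ORF5+, at the stages S1, S2 and S3. Each of the 9 groups held 2 libraries. ORF3 and ORF5 belong to the S5 hybrid sterility locus, where ORF5+, an aspartic protease, acts together with ORF4+ against female gametes and ORF3+, a member of the Hsp70 family, protects them. Depth was known only through the deposited intervals, which imply 18060000 to 27960000 fragments per library, with Balilla S1 replicate 2 the deepest. Between 18775 and 21255 genes per library had an FPKM of at least 1. In each of the 119 calls on the named genes between groups of a single stage or between Balilla stages, both libraries of 1 group lay beyond both libraries of the other, but since the calls were picked by a test for such differences this adds no separate evidence (chance gives it for 33.3% of unselected genes).

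ORF5 was higher in each transgenic library than in each Balilla library, and ORF3 was highest in BalillaORF3+ORF5+. ORF5 (LOC_Os06g11010, chromosome 6, 5759685 to 5761518) stood at 0.604 to 1.16 FPKM in the 6 Balilla libraries and at 7.01 to 29.7 FPKM in the 12 transgenic ones. Its log2 fold change of BalillaORF5+ against Balilla was 2.71 ± 0.42 at S1, 2.80 ± 0.42 at S2 and 2.86 ± 0.42 at S3, and that of BalillaORF3+ORF5+ was 3.28, 3.15 and 3.80. ORF3 (LOC_Os06g10990, chromosome 6, 5745188 to 5747209) stood at 202.3 to 478.6 FPKM in the 6 BalillaORF3+ORF5+ libraries, and its log2 fold change against Balilla was 6.44 ± 0.18 at S1, 5.28 at S2 and 3.56 at S3. It also rose in BalillaORF5+, whose name gives no ORF3+, by 3.16 ± 0.18 at S1 and 2.52 at S2, and stood 0.66 above Balilla at S3 without passing (adjusted p = 0.0628). In the direct comparison ORF3 rose by a log2 fold change of 3.28 ± 0.18 at S1, 2.76 at S2 and 2.90 at S3, while ORF5 differed by 0.56 ± 0.42, 0.36 and 0.95 and did not pass. ORF3 rose with stage in Balilla, from 1.53 ± 0.0718 FPKM (SD, n = 2) at S1 to 39.4 ± 4.75 at S3. Native and introduced copies share reads, so these values sum both.

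**Figure D1:**
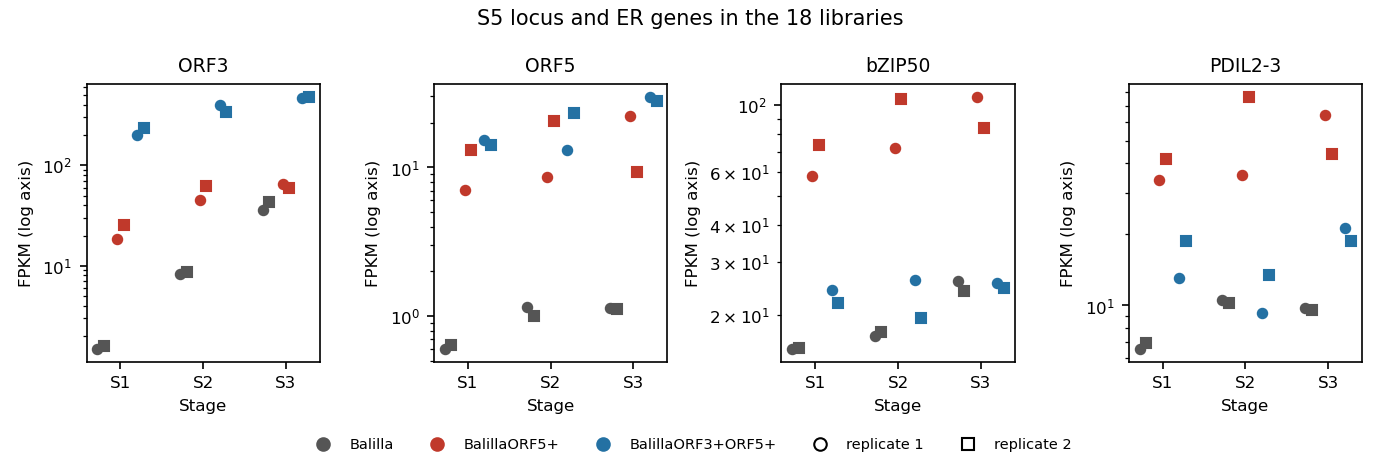
FPKM on log axes of ORF3, ORF5, bZIP50 and PDIL2-3 in the 18 libraries by stage, with colour for genotype and marker shape for replicate. ORF5 lies at or below 1.16 FPKM in Balilla and at or above 7.01 in the transgenic libraries, ORF3 is highest in BalillaORF3+ORF5+, and bZIP50 is highest in BalillaORF5+.

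Balilla alone shows what changed with stage. From S2 to S3, 7 of 8 carpel and ovule genes rose and 1 fell. DL (LOC_Os03g11600), which specifies carpel identity, rose by a log2 fold change of 2.31 ± 0.18, from 33.7 ± 1.02 to 171.8 ± 0.331 FPKM (SD, n = 2), and MADS21 (LOC_Os01g66290), a MADS box gene of ovule and seed, rose by 2.19 ± 0.22. The 3 stamen and lodicule genes MADS4 (LOC_Os05g34940), MADS2 (LOC_Os01g66030) and MADS16 (LOC_Os06g49840), of the B class of floral identity, also rose, MADS4 by 2.22 ± 0.20 and MADS16 by 1.52 ± 0.18. Of 15 meiosis genes, 7 rose and 1 fell. The 1 that fell was DMC1A (LOC_Os12g04980), a meiotic recombinase, which dropped by 2.35 ± 0.17 on the log2 scale to 1.07 ± 0.115 FPKM. In programmed cell death, 4 of 7 genes fell and AP25 (LOC_Os03g08790), an aspartic protease tied to tapetal cell death, rose by 1.19 ± 0.27. In tapetum and pollen, 5 of 10 genes fell while WDA1 (LOC_Os10g33250), needed for anther wax, and C6 (LOC_Os11g37280), an anther lipid transfer protein, rose by 2.09 ± 0.37 and 3.39 ± 0.41. Of 15 ER folding genes, 6 fell and 2 rose, but with any 1 of the 4 libraries left out the rises numbered 0, the meiosis rises numbered 3 to 6, and the cell death falls 2 to 4. From S1 to S2, 6 of 8 carpel and ovule genes (4 with 1 library left out), 3 of 3 stamen and lodicule genes (2 with 1 library left out) and 4 of 10 tapetum genes (3 to 4) rose, while 1 tapetum gene fell, TIP2 (LOC_Os01g18870), a transcription factor of the tapetum, by 2.06 ± 0.43. Of the meiosis genes PAIR2 (LOC_Os09g32930), a protein of the meiotic chromosome axis, rose by 0.74 ± 0.22 and DMC1A fell by 0.62 ± 0.17, and each call was lost in 3 of 4 fits with 1 library left out. Of the cell death genes AP25 rose by 2.85 ± 0.27, and 0 of 15 ER genes passed limma's test (4 at unadjusted p under 0.05).

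Over all genes, 14682 changed from S2 to S3 (10025 higher, 4657 lower) and 6924 from S1 to S2 (5830 higher, 1094 lower). Leaving out 1 library brought the count from S1 to S2 to between 2740 (without Balilla S1 replicate 1) and 4664 (without Balilla S1 replicate 2), and quantile normalization brought it to 3984, while the 4 libraries of the comparison alone gave 14585. With quantile normalization the median log2 fold change of all genes moved from 0.26 to 0.01 between S1 and S2 and from 0.37 to 0.24 between S2 and S3, well below the rises of DL, MADS4 and MADS21. On the line from the Balilla S1 mean (0) to the Balilla S3 mean (1), the Balilla S2 libraries lay at 0.316 and 0.322, as the plot of library positions shows.

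**Figure D2:**
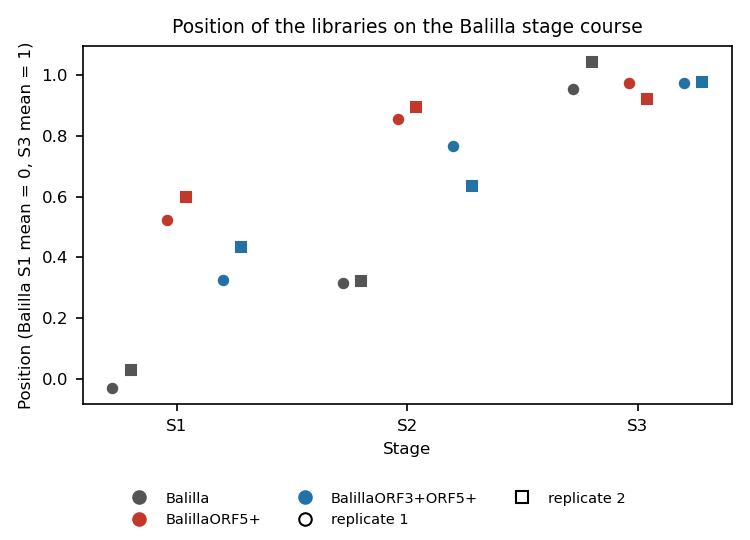
Position of each library on the Balilla stage course (no unit, the Balilla S1 mean is 0 and the Balilla S3 mean is 1) by stage, with colour for genotype and marker shape for replicate. At S1 and S2 the transgenic libraries lie above Balilla of the same stage, and at S3 the 6 libraries lie between 0.922 and 1.04.

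BalillaORF5+ against Balilla asks what differs between pistils of the genotype with ORF5+ and of its parent. These groups also differed in mean position on the Balilla stage course, 0.561 against 0 at S1 and 0.876 against 0.319 at S2. A difference at S1 or S2 may therefore come from position as well as from ORF5+. Effects of the transformation itself cannot be told apart from those of ORF5+ here. Among floral identity genes, DL rose by a log2 fold change of 2.12 ± 0.18 at S1 and 1.83 at S2, MADS4 by 2.81 ± 0.20 and 1.89, and MADS16 by 1.16 ± 0.18 and 1.07. Of the 8 carpel and ovule genes, 3 rose and 1 fell at S1, where their median of 0.29 lay below the 0.42 of all genes, and 6 rose at S2, and of the stamen and lodicule genes 3 of 3 rose at both stages. DL reached 58.3 ± 9.44 FPKM at S1 against 12.6 ± 1.79 in Balilla (SD, n = 2), a level that Balilla passed only at S3. Of 15 meiosis genes, 10 rose and 1 fell at S1, and 9 rose and 2 fell at S2. PAIR2 rose by 1.87 ± 0.22 at S1, and MEL1 (LOC_Os03g58600), a germ cell Argonaute, by 3.12 ± 0.37, while DMC1A fell by 1.53 ± 0.17 at S1 and 2.48 at S2.

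Cell death and tapetum genes moved both ways in the same comparison. AP25 rose by 4.31 ± 0.27 at S1, from 2.32 ± 1.82 to 59.6 ± 0.711 FPKM, and by 1.86 at S2, while the vacuolar processing enzymes VPE2 (LOC_Os01g37910) and VPE3 (LOC_Os02g43010) fell by 1.46 ± 0.28 and 1.05 ± 0.26 at S1. Of 7 cell death genes, 2 rose and 3 fell at S1 and 1 rose and 3 fell at S2. Of 10 tapetum and pollen genes, 5 rose and 1 fell at S1 and 6 rose and 1 fell at S2. WDA1 rose by 3.26 ± 0.37 at S1, and TIP2 by 2.10 ± 0.43. Adjusted over the list alone the counts were the same at S1 except for a second meiosis gene that fell, and at S2 11 meiosis and 7 carpel genes rose. Camera set none of the 6 lists apart from all other genes at S1 (adjusted p from 0.378 to 0.697) or S2 (from 0.148 to 0.558).

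Of 23503 tested genes, 14476 changed at S1 (10721 higher, 3755 lower) and 13572 at S2 (9609 higher, 3963 lower). With 1 library left out the counts were 11198 to 12463 at S1 and 10500 to 11678 at S2. How many genes counted as higher depends on scaling: quantile normalization, which gives every library the same distribution, moved the median log2 fold change of all genes from 0.42 to 0.02 at S1 and from 0.35 to 0.16 at S2, and the S1 genes that passed then split into 6233 higher and 6019 lower. DL, MADS4, AP25 and MEL1 rose at S1 by far more than this shift. MADS2 rose at S1 by 0.39 ± 0.13, less than the median of all genes, and lost its call with quantile normalization (adjusted p = 0.0782) and without either Balilla S1 library or BalillaORF5+ S1 replicate 2 (adjusted p up to 0.169), and MADS21, which rose by 0.91 ± 0.22, stood at 0.25 and lost its call with quantile normalization (adjusted p = 0.411). With any 1 of 4 libraries left out the list counts at S1 stayed within 1 of those given, and with quantile normalization 7 meiosis genes rose at S1. At S2, with any 1 of the 4 libraries left out, the meiosis rises numbered 4 to 6, the carpel rises 3 to 4 and the tapetum rises 3 to 7.

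**Figure D3:**
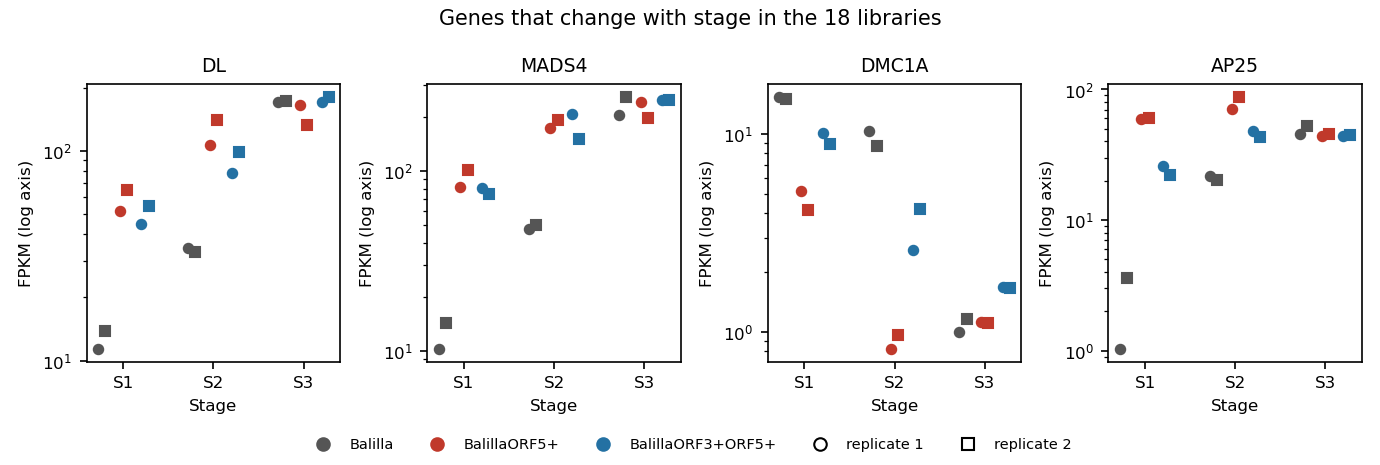
FPKM on log axes of DL, MADS4, DMC1A and AP25 in the 18 libraries by stage, with colour for genotype and marker shape for replicate. DL, MADS4 and AP25 are higher and DMC1A lower in the transgenic libraries than in Balilla at S1 and S2, and at S3 their log2 fold changes against Balilla lay between -0.22 and 0.37.

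At S3 the change in BalillaORF5+ was small in number and included the ER folding genes. Of 15 ER genes 8 rose and 0 fell, 10 at unadjusted p under 0.05 and 10 adjusted over the list alone. bZIP50 (LOC_Os06g41770, chromosome 6, 25041772 to 25044111), a transcription factor of the unfolded protein response, rose by a log2 fold change of 1.88 ± 0.19, from 25 ± 1.29 to 95.2 ± 16.1 FPKM (SD, n = 2). PDIL2-3 (LOC_Os09g27830, chromosome 9, 16930987 to 16935970), a protein disulfide isomerase, rose by 2.34 ± 0.30. These genes were also higher at the earlier stages, bZIP50 by 2.01 at S1 and 2.27 at S2 and PDIL2-3 by 2.33 and 2.23. Over the ER list 8 rose and 2 fell at S1, and 7 rose and 2 fell at S2. IRE1 and bZIP60 of this list stood lower than Balilla in both BalillaORF5+ libraries at both of these stages. IRE1 had 31.68 and 25.21 FPKM at S1 against 58.91 and 60.69 in Balilla, and bZIP60 40.88 and 35.97 against 58.87 and 57.99. The authors' deposited tables mark IRE1, bZIP60 and CRT3 as significantly lower in BalillaORF5+ at S1 and S2. These genes are named after their values were seen. The median log2 fold change of the list was 0.73, 0.56 and 0.78 at the 3 stages, against 0.42, 0.35 and 0.01 for all genes. With 1 library left out the list stood at 0.61 to 0.82 at S1, 0.17 to 0.96 at S2 and 0.71 to 0.85 at S3, so at S2 it fell below the median of all genes without BalillaORF5+ S2 replicate 2.

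Camera set the ER list apart from other genes at S3 (adjusted p = 1.11e-08, and adjusted p = 0.0752 with an estimated correlation). The 8 rises became 3 without Balilla S3 replicate 2 or without BalillaORF5+ S3 replicate 2 and 5 without either of the other libraries, and 5 after rescaling to equal sums. PDIL1-1 (LOC_Os11g09280), another disulfide isomerase, rose by 0.78 ± 0.15, and lost its call without Balilla S3 replicate 2 or BalillaORF5+ S3 replicate 2, with adjusted p up to 0.183.

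Of the other lists, the carpel list had 1 gene past the threshold at S3 in BalillaORF5+, MADS29 (LOC_Os02g07430), which fell by 0.93 on the log2 scale and is named, after its value was seen, because the count was 1; with 1 library left out the count was 0 or 1. The cell death, meiosis, stamen and tapetum lists had 0 genes past limma's threshold, with 2, 0, 0 and 1 genes at unadjusted p under 0.05. In the tapetum list C6 stood 1.115 above Balilla on the log2 scale (0.48 to 1.75 with 1 library left out), and the authors' deposited table marks it as significantly higher. DL differed from Balilla by -0.22 ± 0.18, MADS4 by -0.08 ± 0.20, DMC1A by 0.03 ± 0.17 and AP25 by -0.12 ± 0.27. In all, 859 genes changed at S3 (600 higher, 259 lower), with 65 to 1420 when 1 library was left out, the fewest without BalillaORF5+ S3 replicate 2 and the most without BalillaORF5+ S3 replicate 1. With the 4 libraries of the comparison alone limma called 0 genes at S3 (3994 at unadjusted p under 0.05).

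**Figure D4:**
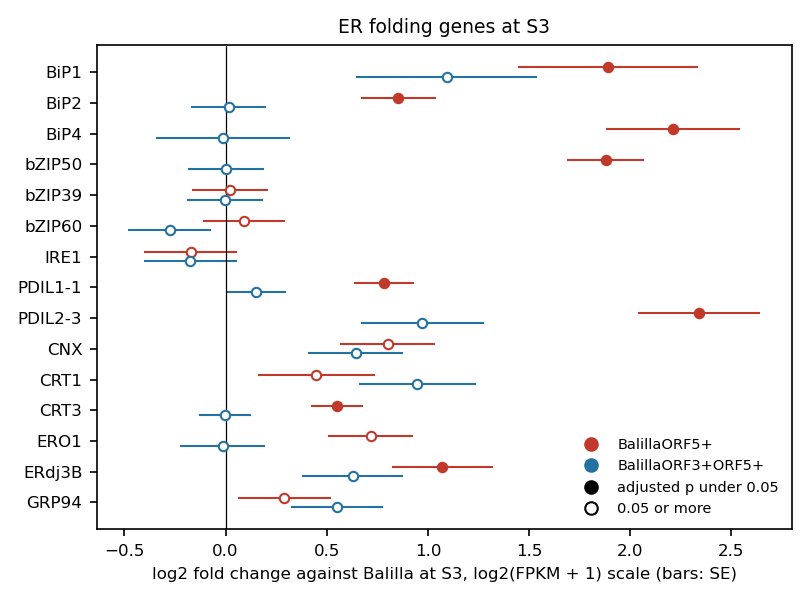
Log2 fold change against Balilla at S3 (horizontal axis, log2(FPKM + 1) scale) of 15 ER folding genes in BalillaORF5+ and BalillaORF3+ORF5+, with bars for the standard error and filled points for adjusted p under 0.05. In BalillaORF5+ 8 genes are filled, and in BalillaORF3+ORF5+ 0 passed limma's test, with 6 at unadjusted p under 0.05.

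BalillaORF3+ORF5+ against Balilla asks what differs from the parent when the protector is present beside ORF5+. Here too the mean positions on the Balilla stage course differed, 0.38 against 0 at S1 and 0.701 against 0.319 at S2. Position and the transformation itself may therefore add to these differences. Among floral identity genes at S1 and S2, DL rose by a log2 fold change of 1.89 ± 0.18 and 1.36, MADS4 by 2.59 ± 0.20 and 1.84, and MADS16 by 0.91 ± 0.18 and 0.84. AP25 rose by 3.03 ± 0.27 at S1 and 1.09 at S2, PAIR2 by 1.69 ± 0.22 and 1.15, and WDA1 by 2.55 ± 0.37 at S1. VPE2 fell by 1.86 ± 0.28 and DMC1A by 1.29 ± 0.17 at S2. Of the 15 meiosis genes, 9 rose and 2 fell at S1, and 2 rose and 2 fell at S2. The carpel list had 3 rises among 8 genes at S1 and 5 rises and 1 fall at S2, the stamen list 3 of 3 rises at both stages, the cell death list 1 rise and 2 falls at both, and the tapetum list 4 rises at S1 and 1 rise and 1 fall at S2. Adjusted over the list alone, the tapetum list had 0 at S2 by limma (5 at unadjusted p under 0.05), the meiosis list 10 rises at S1 and 1 fall at S2, and the carpel list 1 fall at S1. With 1 library left out the rises numbered 6 to 10 for meiosis, 1 to 2 for carpel and 2 to 6 for tapetum genes at S1, and 1 to 7 for meiosis and 0 to 3 for tapetum genes at S2.

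Of the 15 ER genes in this genotype, 5 rose and 1 fell at S1, at S2 1 rose and 5 fell, and at S3 0 passed limma's test (6 at unadjusted p under 0.05). bZIP50 stood at 23.1 ± 1.67, 22.9 ± 4.73 and 25 ± 0.653 FPKM at the 3 stages, with a log2 fold change against Balilla of 0.37 ± 0.19 at S2 and 0.00 ± 0.19 at S3. Its rise of 0.54 ± 0.19 at S1 lost its call with any 1 of the 4 libraries left out (adjusted p from 0.0882 to 0.133) and had a log2 fold change of 0.27 with quantile normalization. PDIL2-3 rose by 1.11 ± 0.30 at S1, which became 0.67 (adjusted p = 0.110) with quantile normalization and lost its call without Balilla S1 replicate 1 or BalillaORF3+ORF5+ S1 replicate 2 (adjusted p up to 0.112), and stood 0.97 ± 0.30 above Balilla at S3 without passing. At S3 the 6 ER genes at unadjusted p under 0.05 lay above Balilla, by 0.55 (GRP94) to 1.09 (BiP1). The ER rises at S1 numbered 1 to 4 when 1 library was left out and 2 with quantile normalization, and the falls at S2 numbered 3 to 6.

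At S2 camera set the ER list lower (adjusted p = 0.0380, and adjusted p = 0.459 with an estimated correlation) and the stamen and lodicule list higher (the same adjusted p values) than other genes. Each of these calls was lost without Balilla S2 replicate 2, BalillaORF3+ORF5+ S2 replicate 1 or BalillaORF3+ORF5+ S2 replicate 2, with adjusted p up to 0.124 for the ER list and 0.123 for the stamen list. The 2 BalillaORF3+ORF5+ S2 libraries stood apart from each other, with a correlation across genes of 0.923 against 0.963 to 0.995 in the other groups. In this genotype camera gave adjusted p of 0.109 or more for each list at S1, 0.224 or more for the other lists at S2 and 0.0688 or more at S3 (0.0414 for the ER, meiosis and stamen lists with quantile normalization), where 0 genes of any list passed limma's threshold (6 ER genes and 1 stamen gene at unadjusted p under 0.05).

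Over all genes, 9938 changed at S1 (8056 higher, 1882 lower), 10856 at S2 (7655 higher, 3201 lower) and 79 at S3 (50 higher, 29 lower). Leaving out BalillaORF3+ORF5+ S1 replicate 2 gave 5503 at S1, leaving out Balilla S2 replicate 1 gave 6689 at S2, and the count at S3 was 13 to 65, lowest without BalillaORF3+ORF5+ S3 replicate 2. With the 4 libraries of each comparison alone limma called 0 genes at S2 (8228 at unadjusted p under 0.05) and 5 at S3. Quantile normalization moved the median log2 fold change of all genes from 0.30 to -0.01 at S1 and from 0.24 to 0.09 at S2.

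**Figure D5:**
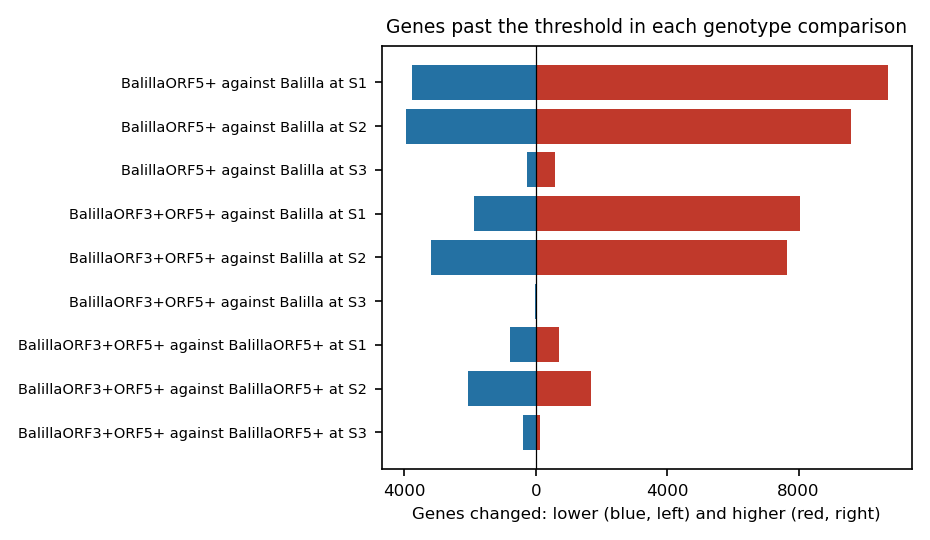
Number of genes past the threshold in each of 9 genotype comparisons (horizontal axis, genes), lower to the left in blue and higher to the right in red. BalillaORF5+ and BalillaORF3+ORF5+ differ from Balilla in 9938 to 14476 genes at S1 and S2 and in 859 and 79 genes at S3.

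The direct comparison of BalillaORF3+ORF5+ with BalillaORF5+ asks what differs between the genotypes with and without ORF3+. These also differed in mean position on the Balilla stage course, 0.38 against 0.561 at S1 and 0.701 against 0.876 at S2. A direct difference at S1 or S2 may therefore come from position as well as from ORF3+. Of 15 ER folding genes 4 fell at S1, 6 at S2 and 6 at S3, and 0 passed limma's test as higher (7, 12 and 7 at unadjusted p under 0.05 in either direction). bZIP50 was lower by a log2 fold change of -1.47 ± 0.19 at S1, -1.90 ± 0.19 at S2 and -1.88 ± 0.19 at S3, 66.0 ± 10.8 FPKM against 23.1 ± 1.67 at S1 (SD, n = 2). PDIL2-3 was lower by -1.22 ± 0.30, -2.13 ± 0.30 and -1.37 ± 0.30. Adjusted over the list alone 6 ER genes fell and 1 rose at S1, 12 fell at S2 and 7 fell at S3. Camera set the ER list below other genes at S2 (adjusted p = 5.26e-05, and adjusted p = 0.282 with an estimated correlation) and S3 (adjusted p = 1.18e-06, and adjusted p = 0.148 with an estimated correlation), but not at S1 (adjusted p = 0.334).

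The bZIP50 calls lasted with each library left out. With 1 library left out the number of ER genes that fell was 1 to 4 at S1, 4 to 11 at S2 and 1 to 3 at S3, and at S3 PDIL2-3 (adjusted p from 0.0969 to 0.280) and PDIL1-1, lower by -0.63 ± 0.15 (adjusted p from 0.0799 to 0.391), lost their calls without any 1 of the 4 libraries. The PDIL2-3 call at S1 was lost without either BalillaORF5+ S1 library or BalillaORF3+ORF5+ S1 replicate 1 (adjusted p up to 0.291). After rescaling to equal sums 3 ER genes fell at S3.

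With all libraries, few genes of other lists differed directly. At S2 this hung on single libraries: with 1 left out the median log2 fold change ran from -0.94 to -0.12 for the meiosis list. For the cell death list it ran from -0.69 to 0.32, for the tapetum list from -1.13 to 0.17 and for the carpel list from -0.27 to -0.11. DMC1A was higher in BalillaORF3+ORF5+ by 0.91 ± 0.17 at S1 and 1.19 ± 0.17 at S2, and AP25 was lower by -1.28 ± 0.27 at S1, a call that any 1 of the 4 libraries left out ended (adjusted p from 0.0524 to 0.162). The DMC1A call at S1 was lost without BalillaORF5+ S1 replicate 2 or BalillaORF3+ORF5+ S1 replicate 1, with adjusted p up to 0.167. C6 was lower at S2 by -2.76 ± 0.41. WDA1 was lower at S2 by -1.54 ± 0.37, and lost its call without BalillaORF5+ S2 replicate 1 or BalillaORF5+ S2 replicate 2, with adjusted p up to 0.0894. VPE3 was higher at S2 by 1.02 ± 0.26, which passed in 1 of 4 fits with 1 library left out, the one without BalillaORF3+ORF5+ S2 replicate 2. At S3 1 carpel gene, MADS29, was higher by 0.88, and 0 to 1 carpel genes were higher when 1 library was left out. The stamen list had 0 genes past limma's threshold at all 3 stages (0 at unadjusted p under 0.05), and camera gave adjusted p of 0.257 or more for lists other than the ER one. Over the 54 list tests the median, the mean and camera differed in sign in 11, none of which passed.

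Over all genes the direct comparison gave 1481 changed at S1 (703 higher, 778 lower), 3738 at S2 (1672 higher, 2066 lower) and 541 at S3 (137 higher, 404 lower). These counts hang on single libraries: 100 without BalillaORF5+ S1 replicate 2 at S1, 1553 without BalillaORF5+ S2 replicate 2 and 10414 without BalillaORF3+ORF5+ S2 replicate 2 at S2, and 96 without BalillaORF3+ORF5+ S3 replicate 2 at S3. With the 4 libraries of each comparison alone limma called 2 at S1, 0 at S2 (2620 at unadjusted p under 0.05) and 234 at S3.

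Averaged over the stages, 15500 genes differed between BalillaORF5+ and Balilla (11208 higher, 4292 lower), 12548 between BalillaORF3+ORF5+ and Balilla (9341 higher, 3207 lower), and 5208 between the transgenic genotypes (2070 higher, 3138 lower). A fit of genotype and position on the Balilla stage course, without stages, was chosen after seeing the data. In place of the first count it gave 6037 (3329 higher, 2708 lower), with 374 of the 4586 genes called in both fits reversed. In place of the next it gave 478 (359 higher, 119 lower), with 2 of 414 reversed. Among genes without a known name, LOC_Os02g10830 (chromosome 2, 5748604 to 5749500) rose in the mean of BalillaORF5+ by 4.37 ± 0.27, with 13.1, 26.7 and 34.2 FPKM at the 3 stages and at most 0.337 FPKM in any group of the other genotypes. LOC_Os05g10210 rose by 3.82 ± 0.32, and at S1 it also stood higher in BalillaORF3+ORF5+ (39.7 FPKM) than in Balilla (1.28 FPKM). LOC_Os08g08970 was lower by -5.03 ± 0.76 and LOC_Os05g15770 by -4.90 ± 0.52. In Balilla itself both rose from S1 to S2, from 883.2 to 2222 and from 416.7 to 1240 FPKM. From S2 to S3 they fell there to 7.39 and 22.9 FPKM. Both were lower in BalillaORF3+ORF5+ too, at S1 205.4 against 883.2 and 58.8 against 416.7 FPKM in Balilla. Quantile normalization moved the median log2 fold change of all genes from 0.26 to 0.04 in the mean of BalillaORF5+ and from 0.19 to 0.01 in that of BalillaORF3+ORF5+. The mean of the direct difference was 3360 genes without BalillaORF5+ S1 replicate 2 and 9680 without BalillaORF3+ORF5+ S2 replicate 2.

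In BalillaORF5+ 344 genes passed as higher and 89 as lower at all 3 stages, among them ORF5, bZIP50 and PDIL2-3 on the higher side, and in BalillaORF3+ORF5+ 23 passed as higher and 10 as lower. These counts are capped by the few calls at S3. Among genes that passed in the mean and had a group mean of at least 5 FPKM, both BalillaORF5+ libraries lay above both Balilla libraries at every stage for 3448 and below them for 1186, and for BalillaORF3+ORF5+ the counts were 2846 and 752 (chance gives 0.926% of unselected genes). Since these genes were picked by a test for such differences, the separation adds no separate evidence. The limma F test found a genotype difference that changed with stage for 10416 genes in BalillaORF5+ and 5019 in BalillaORF3+ORF5+. For bZIP50 it gave adjusted p of 0.468 and 0.281, and for PDIL2-3 0.971 and 0.163. The count of 5019 was 1362 without BalillaORF3+ORF5+ S3 replicate 1, 13472 without BalillaORF3+ORF5+ S2 replicate 2, and 3042 with quantile normalization.

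The transgenic genotypes were compared with the same Balilla libraries, so their differences from Balilla share an error. Across genes the correlation of both sets of log2 fold changes was 0.922 at S1, 0.818 at S2 and 0.468 at S3, and simulated unchanged groups with shared controls gave 0.499, 0.5 and 0.5. The covariance exceeded the simulated one by 0.692, 0.685 and 0.043. Genes are not independent replicates, and with 2 controls per stage part of the excess can come from these controls. The sign was the same in 90.8%, 83.0% and 68.6% of genes, against 66.7% in the simulation. Genes that passed as higher in both genotypes numbered 7771, 6207 and 10, those lower in both 1723, 2695 and 9, and those opposite 11, 30 and 1, and no value for unchanged groups with shared controls was computed for these counts (the planned value for independent lists is left out, since the lists share controls).

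In the authors' deposited table for BalillaORF5+ at S1, 13355 genes were significant, 6551 higher and 6804 lower. Of those tested here, 97.1% had the same direction and 76.8% passed the limma threshold. In the authors' deposited tables for the other 5 comparisons, 504 to 9001 genes were significant and 100% of those tested here had the same direction. Their balance was another one: 3806 higher and 5195 lower for BalillaORF5+ at S2, 436 and 131 at S3, and 2677 and 1950, 104 and 678, and 263 and 241 for BalillaORF3+ORF5+ at S1, S2 and S3. The surplus of higher genes found here was thus turned around in 3 of the 6 tables, those of BalillaORF5+ at S1 and S2 and of BalillaORF3+ORF5+ at S2. The share that passed the limma threshold was 85.0% for BalillaORF5+ at S2, 59.6% for BalillaORF5+ at S3, and 85.8%, 97.3% and 11.2% for BalillaORF3+ORF5+ at S1, S2 and S3. The other way round, 68.7%, 55.3% and 39% of the BalillaORF5+ calls made here at S1, S2 and S3 were significant in the authors' deposited tables. For BalillaORF3+ORF5+ these shares were 39.4%, 7% and 69.6%. Both sets of calls rest on the same libraries. At S3 the authors' deposited table for BalillaORF5+ lists bZIP50, PDIL2-3, BiP1, BiP2 and BiP4 as significantly higher, and the authors' deposited table for BalillaORF3+ORF5+ lists PDIL2-3, BiP1 and CRT1 as significantly higher, so ER genes were called in both genotypes there. BiP1, BiP2, BiP4 and CRT1, ER chaperone genes, are named after their values were seen.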

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

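The tests of developmental position, of scaling, of tapetal cells and of a few abundant genes in this part were chosen only after the results they concern were seen, while those of depth and gene length were written down before.

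For 24 combinations of a named gene and a genotype, the limma F test found that the difference from Balilla was not the same at the 3 stages. In BalillaORF5+ the adjusted p was 1e-04 for ORF3, 7.2e-05 for AP25, 0.0018 for VPE2, 1e-04 for DMC1A, 0.00067 for PAIR2, 0.0075 for MEL1, 0.00012 for DL, 0.0096 for MADS21, 8.8e-05 for MADS4, 0.0059 for MADS2, 0.0082 for MADS16, 0.0045 for WDA1, 0.045 for C6 and 0.048 for TIP2. In BalillaORF3+ORF5+ it was 0.0012 for ORF3, 0.0018 for AP25, 0.015 for VPE2, 0.0038 for DMC1A, 0.0098 for PAIR2, 0.017 for MEL1, 0.0026 for DL, 0.026 for MADS21, 0.0014 for MADS4 and 0.015 for WDA1. DL, for example, was 2.12 above Balilla at S1 in BalillaORF5+ and -0.22 from it at S3, and AP25 4.31 and -0.12.

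These genes follow a wider pattern: 9938 to 14476 genes differed from Balilla at S1 and S2 and 859 or 79 at S3. A difference in depth is argued against by the top 25% of genes by mean FPKM, of which 63.3% passed for BalillaORF5+ at S1, and scaling as the whole cause by the 12252 genes that passed at S1 with quantile normalization. Scaling and a true surplus of higher genes at S1 cannot be told apart: the share of higher genes fell from 74.1% to 50.9% with quantile normalization, which gives every library the same distribution and so takes out a true surplus as well (the test was set to open for this reason after its value was seen), and the authors' deposited table lists 6551 higher and 6804 lower. A candidate explanation is that transgenic pistils at S1 and S2 stood further along development than Balilla pistils of the same label: across genes the BalillaORF5+ difference at S1 correlated with the change in Balilla from S2 to S3, which shares no library with it, at 0.755. Whether the genotype or the time of sampling moved them, and how much of the difference position takes up, stays open. Other organs or cells in the samples, for which the stamen and tapetum lists stood, were not tested for this pattern. In BalillaORF5+ 3 of 3 stamen and lodicule genes rose at S1 and at S2. Of 10 tapetum and pollen genes, 5 rose and 1 fell at S1, and 6 rose and 1 fell at S2. Camera set neither list apart from other genes, and the stamen genes also rose with stage in Balilla. A different share of other organs or cells therefore stays open as well.

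ER folding genes were higher in BalillaORF5+ at S3, with a median log2 fold change of 0.78 against 0.02 in BalillaORF3+ORF5+ (0.03 to 0.20 with 1 library left out), where 6 genes lay 0.55 to 1.09 above Balilla at unadjusted p under 0.05 and the list passed with quantile normalization (adjusted p = 0.0414), and the direct comparison of the transgenic genotypes passed for the list at S3 (adjusted p = 1.18e-06, and 0.148 with an estimated correlation). A shift along the Balilla stage course is argued against by the median of 0.038 it predicts for the list at S3. This prediction scales the Balilla change from S2 to S3 by the small gap in mean position, 0.948 against 1. It is therefore small for any list, and it does not cover development that leaves this line. Tapetal cells and a response to ORF5+ cannot be told apart, since 8 of the 10 tapetum and pollen genes (list median 0.25) averaged under 5 FPKM in both groups. That bound was set after their values were seen. The others, WDA1 and C6, stood 0.66 ± 0.37 and 1.12 ± 0.41 above Balilla without passing. C6 ran from 0.48 to 1.75 with 1 library left out, and the authors' deposited table marks it as significantly higher. A first version of the scaling test counted genes, found that 5 of 8 passed under quantile normalization and under rescaling to equal sums, and decided nothing, so the median was tested instead, and it stayed at 0.73 or more under both. A response of ER folding to ORF5+ that is weaker with ORF3+ stays open as a hypothesis, since it was found and tested on the same libraries. The list test misses the threshold with an estimated correlation (adjusted p = 0.0752), so fewer genes than 15 may carry independent evidence.

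The pair of BalillaORF3+ORF5+ S2 libraries differed more than any other pair, with a mean squared difference of 186.86 in units of the interval error against 1.56 to 76.77 elsewhere. Replicate 1 had a sum of FPKM of 715174 against 586523 in replicate 2, and its top 10 genes held 8.36% of the sum against 4.53%. A few abundant genes as the cause are argued against by the median absolute log2 difference, which was 0.441 after both libraries were shifted to the same median (at most 0.199 in the other pairs). Developmental position as the main cause is argued against by a correlation of 0.318 with the Balilla change from S1 to S3, or 10.1% of the variance. The bounds for this test were set after the value was seen, and a part is not excluded, since replicate 1 lay at 0.768 and replicate 2 at 0.634 on the stage course. A bias with gene length is consistent with the rank correlation of -0.339 across genes between locus length and the difference of replicate 1 from replicate 2, the shortest 25% of loci standing at a median of 0.22 and the longest 25% at -0.39. The Balilla S1 and S2 pairs had -0.224 and -0.226 with small differences, and locus length includes introns. No biological explanation other than developmental position was tested, so the source stays open.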

How the results depend on the processing

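The fits without both BalillaORF3+ORF5+ S2 libraries, those with position as a covariate, and the list tests with a library left out were chosen only after the results were seen. A pseudocount of 0.1, rescaling to equal sums and the replicate block kept each of the 16 counts within 1.5 times its value and each of the 54 list tests on its side of the threshold. Replicate numbers did not pair the libraries: of 36 pairs of groups, 9 had a correlation of their replicate differences over 0.1 (median 0.022), and the block made 1 call on a named gene stronger and 1 weaker. Over all settings, 2298 values of named genes kept their side of the threshold, 124 lost their call, 33 gained one and 1 reversed. A change of sign counted as a reversal only where the main fit or the other fit called the gene. Signs of uncalled genes did change: MADS21 in BalillaORF5+ at S3 ran from -0.56 to 0.12 with 1 library left out. The reversed one was TIP2 in the direct comparison at S1, 0.93 without BalillaORF3+ORF5+ S1 replicate 1 and -1.04 without BalillaORF3+ORF5+ S1 replicate 2, against -0.05 with all libraries. Rescaling to equal sums moved the median log2 fold change of all genes to 0.53 for BalillaORF5+ at S1, to -0.18 for the direct comparison at S2 and to 0.47 for Balilla from S2 to S3.

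With the 4 libraries of a comparison alone, the residual degrees of freedom were fewer and the spread was that of these libraries. limma then called 0 genes for BalillaORF5+ at S3 (3994 at unadjusted p under 0.05), 0 for BalillaORF3+ORF5+ at S2 (8228), 0 for the direct comparison at S2 (2620) and 2 at S1, 5 for BalillaORF3+ORF5+ at S3, 234 for the direct comparison at S3, and 14585 for Balilla from S1 to S2. The counts rose to 17542 for BalillaORF5+ at S1 and 15183 at S2, so fewer degrees of freedom alone do not account for the low counts. With 12 libraries alone the mean direct difference gave 3367 and the stage difference of BalillaORF3+ORF5+ 2655. No filter gave 171 for BalillaORF3+ORF5+ at S3. Quantile normalization gave 3984 for Balilla from S1 to S2 and 3042 for the stage difference of BalillaORF3+ORF5+. Without both BalillaORF3+ORF5+ S2 libraries the counts were 2889 for BalillaORF5+ at S3, 264 for BalillaORF3+ORF5+ at S3, and 4297 and 1045 for the direct comparison at S1 and S3. With position as a covariate in place of the stages, the genotype differences from Balilla were 6037 genes for BalillaORF5+ and 478 for BalillaORF3+ORF5+. The cause was not tested for these last 3 settings.

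With 1 library left out, where the lone library of a group is assumed to vary like the others, the counts ranged from 65 to 1420 for BalillaORF5+ at S3, 5503 to 10079, 6689 to 13460 and 13 to 65 for BalillaORF3+ORF5+ at S1, S2 and S3, 100 to 1595, 1553 to 10414 and 96 to 762 for the direct comparison, 3360 to 9680 for its mean, 2740 to 4664 for Balilla from S1 to S2, and 1362 to 13472 for the stage difference of BalillaORF3+ORF5+. The adjusted p of the ER list ranged from 2.14e-12 to 4.8e-06 for BalillaORF5+ at S3, from 0.0334 to 0.124 for BalillaORF3+ORF5+ at S2, and from 1.52e-06 to 0.00283 and 8.12e-10 to 2.69e-04 for the direct comparison at S2 and S3. That of the stamen list ranged from 0.0334 to 0.123 for BalillaORF3+ORF5+ at S2.

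The estimated correlation ended each of the 5 list calls, with adjusted p of 0.0752 for the ER list of BalillaORF5+ at S3, 0.459 for the ER and stamen lists of BalillaORF3+ORF5+ at S2, and 0.282 and 0.148 for the ER list of the direct comparison at S2 and S3. Quantile normalization ended the call on the ER list of BalillaORF3+ORF5+ at S2 (0.116) and added stamen lists for BalillaORF5+ at S2 (0.0458) and BalillaORF3+ORF5+ at S1 (0.0138), and the ER, meiosis and stamen lists of BalillaORF3+ORF5+ at S3 (0.0414 each). The cause was not tested. Depth, gauged at 18060000 fragments or more, gave no interval for single genes.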

Other observations

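The search for neighbouring genes, the ER genes with position as a covariate and the counts across stages were chosen only after the results were seen, while the splits of the libraries were set before.

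Calls at S3 lay close together on chromosome 10. Among 20 neighbouring tested genes, 10 were higher in BalillaORF5+ than in Balilla at S3, with a median log2 fold change of 3.04, and these 10 spanned 2897616 to 3032720 (135 kb). The same 10 genes were lower in BalillaORF3+ORF5+ than in BalillaORF5+ at S3 (median -3.18), a comparison that shares the BalillaORF5+ S3 libraries and so is no separate evidence. The 10 genes had a median log2 fold change of 3.36 at S1 and 2.20 at S2 in BalillaORF5+, with 9 and 10 of them higher, and of 2.17, 0.39 and -0.14 at S1, S2 and S3 in BalillaORF3+ORF5+, with 8, 1 and 0 higher by limma's adjusted p (8, 2 and 2 at unadjusted p under 0.05). Their median FPKM was 51.5 and 91.1 in the BalillaORF5+ S3 libraries, 5.62 and 7.01 in the Balilla S3 libraries, and 6.33 and 5.97 in the BalillaORF3+ORF5+ S3 libraries. Calls placed at random among the tested genes reached at most 8 and 6 in a window over 10000 permutations, which gave p = 1e-04 for each of these 2 scans, the smallest they can give (adjusted p = 2e-04 over 4 scans). The scans of genes lower in BalillaORF5+ and of genes higher in the direct comparison gave permutation p = 0.23 and permutation p = 1. A cluster of genes under common control, a difference between the transgenic lines at this place, and reads shared between similar genes are candidate explanations beside this value of 1e-04, and none of them was tested.

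Calls at S3 around the S5 locus were counted as well. Within 500 kb of ORF3 and ORF5, 9 of 84 tested genes passed for BalillaORF5+ (3.65% over all genes), 2 for BalillaORF3+ORF5+ (0.34%) and 4 for the direct comparison (2.3%), ORF3 and ORF5 included where they passed; these shares were not tested.

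Other ER chaperones were also higher in BalillaORF5+ in a fit of genotype and position, without stages. With the position of each library on the Balilla stage course as a covariate, 12 of 15 ER genes were higher in BalillaORF5+, and in BalillaORF3+ORF5+ 0 passed limma's test (8 at unadjusted p under 0.05). No Balilla library lay between 0.322 and 0.956 on this course, so the fit bridges that stretch. The 12 include the ER chaperone gene CRT3 (0.49 ± 0.12), named after its value was seen. The authors' deposited tables mark CRT3 as significantly lower in BalillaORF5+ at S1 and S2. The ER chaperone genes BiP1 (LOC_Os02g02410) and BiP4 (LOC_Os05g35400), named after their values were seen, stood at log2 fold changes of 1.98 ± 0.40 and 1.79 ± 0.33 in BalillaORF5+ and at 0.86 ± 0.35 and -0.21 ± 0.29 in BalillaORF3+ORF5+.

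Across stages, and between groups at different positions on the Balilla stage course (0.561 for BalillaORF5+ at S1 and 0.319 for Balilla at S2, for example), BalillaORF5+ at S1 differed from Balilla at S2 in 10313 genes and from Balilla at S3 in 11007, and BalillaORF5+ at S2 differed from Balilla at S3 in 4976. BalillaORF3+ORF5+ at S1 differed from Balilla at S2 in 5299 genes, and BalillaORF3+ORF5+ at S2 from Balilla at S3 in 5171.

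The means over the stages were set beside 100 of the 108 splits of 12 libraries within stages, whose median was 0 genes. Libraries of a group that are not separate plants would resemble each other, so mixing them across genotypes would lower the count in any case. The splits therefore show that libraries of a group resemble each other, and they cannot exclude chance differences between plants. For BalillaORF5+ against Balilla (15500 genes), 2 of the 100 splits gave as many, the real one included. The other, with 15508 genes, kept the labels at S1 and S2 and exchanged them at S3, so it also set the genotypes apart. For BalillaORF3+ORF5+ against Balilla (12548 genes) and for the direct comparison (5208 genes), 1 split gave as many, the real one, and the highest of the others gave 12034 and 2442. In each of the 3 cases the highest of the others kept the labels at S1 and S2. At S3 the labels were exchanged for BalillaORF5+ and mixed in the other cases. The highest count of a split with a mixed stage was 15028 for BalillaORF5+. For the means against Balilla, changed labels at S3 in these splits thus left most of the count in place.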
